A study of Arabidopsis thaliana with 5 samples.

How the data were processed

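RNA was measured in nuclei sorted from root tips of Arabidopsis thaliana seedlings that carried a reporter in which the SMR1 promoter drives a GUS-GFP fusion. Tips of 0.5 cm were cut from seedlings of 5 days, and 120000 GFP-positive nuclei were collected for each library, per the labels' protocols. The labels also name a stranded mRNA library kit. The 5 libraries fell into 2 groups, 2 from Col-0 and 3 from the smr1 mutant, and the series' design text calls them biological replicates. The replicate numbers are those of the labels, 2 and 4 for Col-0 and 1, 2 and 4 for smr1.

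The deposited tables give, for each of 41671 transcript models, an expected count of reads that need not be whole and a TPM value, which is a transcript abundance scaled to the same sum in every library, per the file headers. The deposited expected counts and TPM values stand in columns of the kind Salmon writes, per the file headers. Salmon 0.7.2, CASAVA and the TAIR10 build are named in the submitters' processing notes, without the role of each. The strand setting of the quantification, the read length and any filter on reads are not given in the sources used here. Of the model lengths, 93.36% were multiples of 3, so most models hold coding sequence without untranslated regions, and lengths are called coding lengths here. Reads from an untranslated region, including one carried by the reporter, would then mostly go uncounted. Expected counts divide reads between near-identical models, so values of histone, heat shock, LHCB and ribosomal protein genes are uncertain between family members. The deposited TPM values keep no sequencing depth and were not used for any test.

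Expected counts were summed over the models of each of 33602 loci and rounded to whole numbers. Library totals ranged from 24918795 to 26823753 reads, so 3 reads in a library, taken as the floor of detection, equal between 0.112 and 0.120 CPM, the count scaled by the size of the library. Reads are not independent molecules, and this floor covers counting error only. No pair of libraries held the same values, and chi-square per degree of freedom between pairs lay from 14.8 to 53.5, so no library was counted as a copy of another. The lowest value was between Col-0 replicate 2 and smr1 replicate 2, and the 2 Col-0 libraries had 43.8. Gene symbols came from the RefSeq annotation of TAIR10.1, which matched 32835 of the loci. That assembly differs in name from the build of the labels, and its coordinates are given only for SMR1.

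Genes were tested with edgeR 4.0.16 in R 4.3.3, after its expression filter with a minimum count of 10 and a minimum total of 15, with TMM factors, robust quasi-likelihood F tests on genotype and Benjamini-Hochberg adjustment at 0.05. The fit had 3 residual degrees of freedom. CPM values were scaled by the TMM factors, and standard errors (SE) of log2 fold changes were taken from the F statistic. All tests were two-sided, and fold changes are smr1 relative to Col-0. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and beside it with the correlation estimated for each list and with fry. Lists needed at least 3 tested members. Library levels of a list are means over its members of log2 CPM (prior count 1), relative to the mean of the 5 libraries.

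The design, the lists and the alternatives were fixed before the data were examined. The lists covered CDK inhibitors, G1/S cyclins, DNA replication, G2/M, replication-coupled core histones, endocycle regulators, DNA damage response, primary wall, root hair cells, non-hair epidermis, root cap, cortex, endodermis, pericycle, xylem and secondary wall, phloem, stem cell niche and meristem, photosynthesis, ABA and osmotic stress, wounding and jasmonate, heat shock, iron deficiency, auxin response and cytokinin response. Of 392 members written, 390 were accepted, and SGN3 and PEAR1 were dropped because the annotation gave their loci other symbols. Ribosomal proteins, 328 loci found by their description, were added by a rule fixed at the same time. That description does not exclude every organellar ribosomal protein. Named genes were SMR1, then up to 10 genes per direction past the threshold with groups that did not overlap. Since fewer than 5 genes passed, the rule took the 5 genes with the smallest p per direction as values, and up to 2 members per list where none passed over all genes. Genes named outside this rule are said to be so, and some members that the rule names are not reported here.

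The scripts were tested on simulated counts for the same 20151 genes with known fold changes. With the spread of each gene as estimated, edgeR called 42 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, and 30 of its 165 calls (18.2%) were false, above the nominal rate. With the spread set to its trend over expression, 5 of 152 calls (3.29%) were false, and in the first setting all 30 false calls were among the 4979 unchanged genes whose spread lay highest relative to the trend, with a median ratio of 1.56. DESeq2 1.42.0 had 43 false calls of 185 and limma voom 16 of 136 in the first setting. For lists of independent unchanged genes, 1 of 100 had a camera p under 0.05 with the preset correlation and 9 of 100 had a mixed fry p under 0.05. A list of 25 genes raised 1.5-fold had a camera p of 3.11e-15 with the preset correlation and 0.0100 with an estimated one, before adjustment over lists. Simulated genes were independent, so these lists do not test how the preset correlation performs on genes that vary together.

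Alternatives were RLE, upper-quartile and library-size scaling, no filter, at least 5 CPM in 2 libraries, DESeq2, limma voom, the robust option off, the label numbers as a block, each library left out, organelle genes left out, a test against a fold of 1.5, and the most abundant model of each locus. Leaving out a Col-0 library leaves 1 in that group, whose spread is then assumed to be that of smr1. For the lists the filter was run again each time, so medians do not always cover the same members. The meristem list had 6 tested members with all libraries and 7 without either Col-0 library. Without smr1 replicate 1, photosynthesis had 10 instead of 12 and cytokinin response 7 instead of 9. Iron deficiency had between 6 and 9 instead of 7. Near-identical copies were searched with blastn 2.17.0.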

Results

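The series compared Col-0 with the smr1 mutant in nuclei in which the SMR1 promoter was active. SMR1, also called LGO, encodes a cyclin-dependent kinase inhibitor that promotes endoreplication, the repeated copying of nuclear DNA without division. The comparison addresses which transcripts differ in SMR1-expressing root nuclei when the inhibitor is mutated. There were 2 Col-0 and 3 smr1 libraries. Totals were 25517281 and 26763913 reads for Col-0 replicates 2 and 4, and 24918795, 26823753 and 26805918 reads for smr1 replicates 1, 2 and 4. The 2 Col-0 libraries were not each other's nearest over all genes. Col-0 replicate 2 had its highest correlation of log2 CPM across genes with smr1 replicate 2 (0.987), against 0.976 with Col-0 replicate 4, and genes are not independent replicates. On the first principal component, with 38.3% of the variance, Col-0 replicates 2 and 4 lay at -50.4 and 24.9, and the smr1 libraries between -15.2 and 24.9. On the second, with 28.5%, Col-0 lay at -8.99 and -43.5, and smr1 between 6.80 and 30.3.

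SMR1 (AT3G10525) itself was measured at a lower level in every smr1 library than in either Col-0 library. Its level was 10.97 and 21.6 CPM in Col-0 replicates 2 and 4, from 267 and 577 reads. In smr1 replicates 1, 2 and 4 it was 6.02, 4.70 and 7.06 CPM, from 154, 127 and 192 reads. Means were 16.3 ± 7.54 CPM (SD, n = 2) and 5.93 ± 1.18 CPM (SD, n = 3). The gene lies on chromosome 3 of TAIR10.1 from 3281306 to 3282131 on the minus strand, as a single exon with its coding sequence from 3281576 to 3281962. The log2 fold change was -1.46 with an SE of 0.31, and the difference did not pass the threshold over all genes (edgeR adjusted p = 0.725). DESeq2 gave a log2 fold change of -1.47 with an adjusted p of 0.0115. Without Col-0 replicate 4 the log2 fold change was -0.90. The kind and position of the mutation are not given in the sources used here, so reads that remain in smr1 do not tell whether a functional transcript was made.

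**Figure D1:**
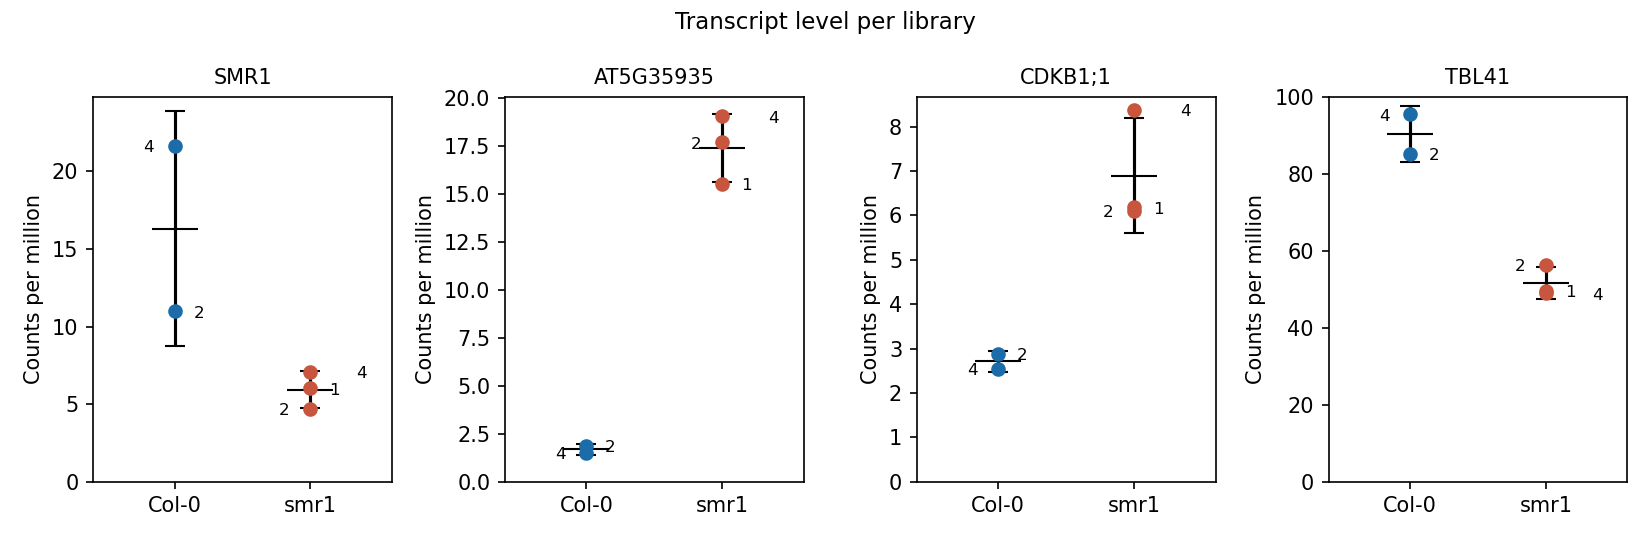
CPM on a linear axis from 0 for SMR1, AT5G35935, CDKB1;1 and TBL41 in the 2 Col-0 and 3 smr1 libraries. Points are libraries marked by replicate number, horizontal lines are group means and error bars are 1 SD. SMR1 lay at 10.97 and 21.6 in Col-0 and between 4.70 and 7.06 in smr1.

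Of single genes, edgeR called AT5G35935 higher in smr1 and none lower, while DESeq2 called 30 higher and 11 lower. AT5G35935, annotated as a pseudogene with another near-identical stretch of 109 nt in the genome, had a mean of 1.69 ± 0.28 CPM (SD, n = 2) in Col-0 and 17.42 ± 1.77 CPM (SD, n = 3) in smr1. Its log2 fold change was 3.36 with an SE of 0.20 (edgeR adjusted p = 0.0217), and it was higher in 3 of 3 smr1 libraries than in both Col-0 libraries. The call was lost without any one of the 5 libraries. The edgeR adjusted p was then 0.113 and 0.157 without Col-0 replicates 2 and 4, and 0.128, 0.168 and 0.470 without smr1 replicates 1, 2 and 4, while the log2 fold change stayed between 3.19 and 3.53. Next by p was AT5G26270, an uncharacterized protein, with a log2 fold change of 1.85 and an SE of 0.16 (edgeR adjusted p = 0.107). AT2G05642, an OB-fold-like nucleic acid-binding protein with a near-identical stretch of 624 nt elsewhere, had 0 reads in both Col-0 libraries and 76, 68 and 63 reads in smr1. Against a floor of 3 reads per library it was at least 22.1-fold higher, with an edgeR adjusted p of 0.109. NOP10, a component of the box H/ACA small nucleolar ribonucleoproteins, had a log2 fold change of 2.45 and an SE of 0.33. MRD1 had a log2 fold change of 2.12 and an SE of 0.29, and both had an edgeR adjusted p of 0.650. DESeq2 called AT5G26270, AT2G05642, NOP10 and MRD1 higher.

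The genes with the smallest p in the lower direction had adjusted p of 0.650 or more by edgeR, while DESeq2 called the 5 named here lower. TBL41, of the TRICHOME BIREFRINGENCE-LIKE family, had 90.3 ± 7.29 CPM in Col-0 and 51.6 ± 4.08 CPM in smr1 (SD). PGSIP5, named as a glycogenin-like starch initiation protein, had a log2 fold change of -0.69 with an SE of 0.10. NSP3, a nitrile specifier protein of glucosinolate breakdown, had -0.85 with an SE of 0.15. RPK1, a receptor-like kinase, had -0.67, and the heme-binding protein SOUL-1 had -0.65, each with an SE of 0.12.

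Over all 20151 genes tested, edgeR called 1 gene higher and 0 lower, with 798 genes higher and 583 lower at an unadjusted p under 0.05, against 1008 in both directions by chance. Other splits of the same libraries into 2 and 3 gave between 135 and 2413 genes at an unadjusted p under 0.05, against 1381 for the genotypes, and 3 of these splits gave more. DESeq2 was run without the expression filter on 26551 genes and gave no adjusted p for 8751 of them, and limma voom called 0. In 2753 genes every smr1 library lay above both Col-0 libraries and in 2045 every one lay below, together 23.8% of genes where chance gives 20%.

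Genes of cell division were higher in smr1 as groups. The replication-coupled core histones, which package newly copied DNA, had a median fold of 1.72, and 23 of 25 members had positive log2 fold changes. The G2/M and cytokinesis list had a median fold of 1.47 with 24 of 28 members positive, and the DNA replication list a median fold of 1.45 with 25 of 27 positive. Of the histones, 22 had every smr1 library above both Col-0 libraries, as had 15 of the G2/M and 19 of the replication genes. Camera called all 3 lists with the preset correlation, with adjusted p of 5.29e-32 for histones, 4.29e-12 for G2/M and 1.24e-13 for replication. All 3 calls were lost with an estimated correlation (adjusted p = 0.408 for each). Over the 24 lists, camera with the preset correlation called 10 between the genotypes, and between 4 and 11 when the same libraries were split in other ways into 2 and 3.

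No member of these lists passed over all genes by edgeR. Of the members named by the rule, DESeq2 called AT5G10400, HIS4, CDKB1;1 and TSO2 higher. Its calls also held at least HIK, HTB2, HTA6 and AT5G59970 of these lists, named after their values were seen. Adjusted over the list alone, 21 of 25 histones, 5 of 28 G2/M genes and 3 of 27 replication genes rose. Histone members varied together, with an estimated correlation of 0.715, and near-identical models divide reads. Their count, here and with a library left out, is therefore not one of independent genes. Among the histones, AT5G10400, an H3 gene, was at 10.98 ± 0.85 CPM in Col-0 and 25.6 ± 5.89 CPM in smr1 (SD). HIS4, an H4 gene, was at 20.3 ± 0.80 and 35.0 ± 4.12 CPM. The G2/M genes past that adjustment were CDKB1;1, CDKB1;2, HIK, CYCB1;2 and CDC20.2, of which the last 3 were named after their values were seen. CDKB1;1, a mitotic cyclin-dependent kinase, was at 2.71 ± 0.23 CPM in Col-0 and 6.89 ± 1.29 CPM in smr1, with a log2 fold change of 1.34 and an SE of 0.23. CDKB1;2 was at 0.215 ± 0.014 and 1.098 ± 0.27 CPM. The replication genes were TSO2, a ribonucleotide reductase subunit, with a log2 fold change of 1.15, ORC3 of the origin recognition complex with 1.38, and CDC6, named after its value was seen, with 0.92. The replication count was 0 without Col-0 replicate 2, Col-0 replicate 4, smr1 replicate 2 or smr1 replicate 4. The G2/M count was 0 without Col-0 replicate 4, 2 without smr1 replicate 2 and 3 without smr1 replicate 4, while the histone count stayed between 16 and 21 without any one library.

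By group medians, markers of the stem cell niche and meristem lay in the same direction as the division genes. Their median log2 fold change was 0.49, with 5 of 6 members positive, and PLT1 and PLT2, transcription factors of the root meristem, had 0.84 and 1.40. PLT2 was at 2.26 without Col-0 replicate 2 and 0.83 without Col-0 replicate 4, from 10 and 4 reads in Col-0 replicates 2 and 4. Camera called the list higher with the preset correlation (adjusted p = 0.00348), and not with an estimated correlation (adjusted p = 0.408). The call was lost without Col-0 replicate 4 (median 0.676, adjusted p = 0.140) and without smr1 replicate 2 (median 0.453, adjusted p = 0.0685), and the median was 1.098 without Col-0 replicate 2. Without either Col-0 library 7 members were tested instead of 6, so those medians do not cover the same genes. The level of the meristem list was 0.09 in Col-0 replicate 2 and -0.02 in smr1 replicate 4 on the log2 scale, so the groups overlapped. Library by library it did not follow the core histones, whose level was highest, at 0.58, in smr1 replicate 4. Col-0 replicates 2 and 4 had histone levels of -0.41 and -0.45, and meristem levels of 0.09 and -0.74.

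Ribosomal protein genes were also higher in smr1 as a group. Their median fold was 1.38 over 302 genes, 280 had positive log2 fold changes, and 178 had every smr1 library above both Col-0 libraries. Camera gave an adjusted p of 2.59e-37 with the preset correlation, while the adjusted p was 0.408 with an estimated correlation. The members with the smallest p were AT1G25260, of the L10 family, with a log2 fold change of 1.11 and an SE of 0.22, and AT2G36160, of the S11 family, with 0.65 and 0.14. Without Col-0 replicate 4 the median log2 fold change was 0.257, against 0.466 with all libraries. By edgeR neither gene passed over all genes, and 0 members passed when adjusted over the list alone, while DESeq2 called AT1G25260 higher (adjusted p = 0.0251).

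**Figure D2:**
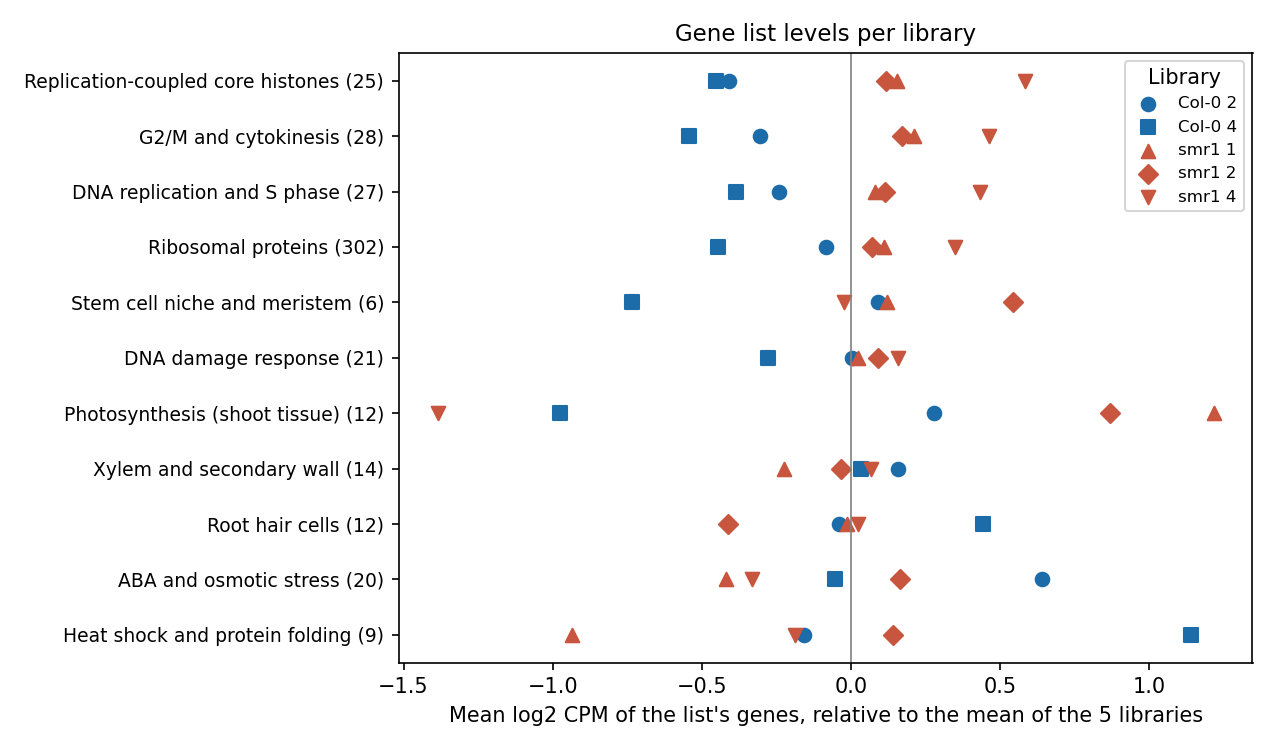
Mean log2 CPM of the genes of 11 lists in each library, relative to the mean of the 5 libraries, with the number of tested genes in brackets. Symbols mark libraries and colours mark genotype. Core histone levels were -0.41 and -0.45 in Col-0 and between 0.12 and 0.58 in smr1, while photosynthesis levels ranged from -1.39 to 1.22 within smr1.

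Of the stress lists, ABA and osmotic stress and heat shock had lower medians in smr1, with uneven libraries. The ABA and osmotic stress list had a median log2 fold change of -0.55 with all 20 members negative, among them SOS3, a calcium sensor of salt tolerance, at -0.71, and ABI1, a phosphatase of ABA signalling, at -0.58. Without Col-0 replicate 2 these 2 genes were at -0.33 and -0.35. The heat shock list had a median of -1.02 with all 9 members negative, and HSP17.4 and HSP17.6II were at -1.53 and -1.48, and at -0.08 and -0.02 without Col-0 replicate 4. Camera called both with the preset correlation (adjusted p = 4.27e-09 and 7.45e-05), and neither with an estimated correlation (adjusted p = 0.408 for each). The ABA call was lost without Col-0 replicate 2, with a median of -0.13 and an adjusted p of 0.128, and the median was -0.83 without Col-0 replicate 4. The heat shock call was lost without Col-0 replicate 4, with a median of -0.02 and an adjusted p of 0.552, and the median was -1.75 without Col-0 replicate 2. HSP17.4 was at 2.92 and 13.01 CPM in Col-0 replicates 2 and 4. Every smr1 library lay below both Col-0 libraries in 4 of the 20 ABA genes and in 0 of the 9 heat shock genes. List levels overlapped between the genotypes. The ABA level was -0.05 in Col-0 replicate 4 and 0.16 in smr1 replicate 2. The heat shock level was -0.16 and 1.14 in Col-0 replicates 2 and 4, and -0.94, 0.14 and -0.19 in smr1 replicates 1, 2 and 4.

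Markers of differentiated root cells were lower or showed no call. The 12 root hair genes were all negative, with a median log2 fold change of -0.36, and ROPGEF3 and EXPA18 at -0.53 and -0.70. In 4 of the 12, every smr1 library lay below both Col-0 libraries. Of the 14 xylem and secondary wall genes 12 were negative, with a median of -0.20, and the cellulose synthases CESA8 and CESA4 were at -0.28 and -0.25. In 7 of the 14, every smr1 library lay below both Col-0 libraries, and in 1 every one lay above. With the preset correlation camera called root hair (adjusted p = 0.00204) and xylem (adjusted p = 0.00540) lower. With an estimated correlation the adjusted p was 0.453 for root hair and 0.470 for xylem. The root hair call was lost without Col-0 replicate 4 (median -0.14, adjusted p = 0.579) or smr1 replicate 2 (median -0.21, adjusted p = 0.0977), and the median was -0.55 without Col-0 replicate 2. The xylem call was lost without Col-0 replicate 2 (median -0.17, adjusted p = 0.0898) or smr1 replicate 1 (median -0.14, adjusted p = 0.145).

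With all libraries, camera called no difference for non-hair epidermis, root cap, endodermis, pericycle or phloem. Median log2 fold changes were 0.16 for non-hair epidermis, where GL2 and WER were at 0.27 and 0.36, -0.02 for root cap, with CEL5 at 0.47 and RNS3 at -0.41, and 0.05 for endodermis, with SCR at 0.18. They were -0.09 for pericycle, with TIP2;3 at -0.84 and LBD16 at 0.28, and -0.02 for phloem, where the mean was 0.14 and camera's direction was higher. In the phloem list CVP2, a phosphatase of vein patterning, rose when adjusted over the list alone, with a log2 fold change of 0.93, and that count was 0 without any one of the 5 libraries. SEOR2 was at 0.35. Without Col-0 replicate 2, TIP2;3, LBD16 and SEOR2 were at -0.20, 0.66 and 0.12, and SCR, WER and CEL5 at -0.10, 0.21 and 0.29. Without Col-0 replicate 4, TIP2;3, LBD16, SEOR2 and SCR were at -1.29, -0.04, 0.61 and 0.50. Without smr1 replicate 1, RNS3 was at -0.24 and SCR at 0.01, without smr1 replicate 2 RNS3 was at -0.65, SCR at 0.33 and LBD16 at 0.13, and without smr1 replicate 4 SEOR2 was at 0.12. The pericycle median was 0.23 without Col-0 replicate 2, 0.29 without smr1 replicate 4 and -0.29 without Col-0 replicate 4. Without smr1 replicate 4 it covers 3 members instead of 4. The phloem median was 0.31 without Col-0 replicate 2, 0.21 without smr1 replicate 1 and 0.09 without Col-0 replicate 4. The root cap median ran from -0.12 without Col-0 replicate 4 to 0.06 without smr1 replicate 1. Of the cortex markers, too few for a test, TBL31 was at -0.23 and PEP at -0.13, and they were at -0.41 and -0.61 without Col-0 replicate 2 and -0.05 and 0.57 without Col-0 replicate 4. Adjusted p by camera was 0.131 for non-hair epidermis, 0.862 for root cap, 0.860 for endodermis, 0.489 for pericycle and 0.362 for phloem. The endodermis list was called in opposite directions when a Col-0 library was left out, lower without replicate 2 (median -0.36, adjusted p = 0.0192) and higher without replicate 4 (median 0.32, adjusted p = 0.00531).

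The DNA damage response list was higher by camera with the preset correlation (adjusted p = 0.0282) and not with an estimated correlation (adjusted p = 0.408). Its median log2 fold change was 0.08 and its mean 0.21, TSO2, which the replication list also holds, was at 1.15 and BARD1 at 0.70. BARD1 was at 1.24 without Col-0 replicate 2 and 0.29 without Col-0 replicate 4. The call was lost without Col-0 replicate 4 (median 0.107, adjusted p = 0.454) and without smr1 replicate 2 (median 0.106, adjusted p = 0.0685), and the median was 0.256 without Col-0 replicate 2. The CDK inhibitor list, which holds SMR1, was not called, with 8 of 20 members positive, a median of -0.10 and AT1G10690 (SMR8) at -0.40 (camera adjusted p = 0.190). It was called lower without Col-0 replicate 2 (median -0.27, adjusted p = 0.0465) and without smr1 replicate 4 (median -0.13, adjusted p = 0.0474), and its median was 0.06 without Col-0 replicate 4.

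The list of G1/S cyclins and their partners, which also holds A2-type cyclins, had a median of 0.08 (camera adjusted p = 0.0888). The A2-type CYCA2;4 and CYCA2;1 were at 1.48 and 1.23, and CYCA2;1 had only 7 and 7 reads in Col-0 and 18, 17 and 17 in smr1. The list median was 0.14 without smr1 replicate 1, -0.02 without Col-0 replicate 4 and -0.01 without smr1 replicate 4. The mixed fry test, which asks whether members change in either direction, gave this list an adjusted p of 0.000948. Endocycle regulators had a median of 0.05 (camera adjusted p = 0.386), with the atypical E2F factor DEL3 at 1.33 and CCS52B at 0.82. Primary wall genes had a median of 0.01 (camera adjusted p = 0.862, direction lower), with XTH14 at -0.84 and XTH5 at 1.06, and the median ran from -0.09 without Col-0 replicate 2 to 0.07 without Col-0 replicate 4. Auxin response had a median of 0.25 (camera adjusted p = 0.0738), with IAA3 at 0.45 (0.12 without Col-0 replicate 2 and 0.88 without Col-0 replicate 4), and was called higher without Col-0 replicate 2 (adjusted p = 0.00221) and without smr1 replicate 1 (adjusted p = 0.00514). Its median was -0.015 without Col-0 replicate 4 and 0.10 without smr1 replicate 2. Cytokinin response had a median of 0.05 (camera adjusted p = 0.479), with ARR7 at 1.95 and ARR15 at 0.81, and was called higher without Col-0 replicate 4 (median 0.31, adjusted p = 0.0248). ARR7 had 1 and 5 reads in Col-0 replicates 2 and 4, near the floor of 3, and 13, 6 and 18 reads in smr1. Its log2 fold change was 1.28 without Col-0 replicate 2. It was 3.34 without Col-0 replicate 4, a value that rests on 1 Col-0 read. ARR15 was at 0.47 without smr1 replicate 1, where the list median was -0.14. Wounding and jasmonate had a median of 0.03 (camera adjusted p = 0.514), with WRKY53 at 0.45 (0.17 without Col-0 replicate 2 and 0.79 without Col-0 replicate 4) and ERF104 at 0.18. It was called higher without Col-0 replicate 2 (median 0.72, adjusted p = 5.61e-08) and lower without Col-0 replicate 4 (median -0.34, adjusted p = 0.00133). Iron deficiency had a median of 0.06 (camera adjusted p = 0.862), with BTS at -0.37 and NAS2 at 0.57, and NAS2 was at 0.36 without Col-0 replicate 2 and 0.33 without smr1 replicate 4. The list median was 0.24 without Col-0 replicate 4 and -0.10, with camera's direction lower, without smr1 replicate 4.

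Photosynthesis genes, markers of shoot tissue, differed between libraries of one genotype. The list level on the log2 scale was 1.22, 0.87 and -1.39 in smr1 replicates 1, 2 and 4, and 0.28 and -0.98 in Col-0 replicates 2 and 4. RBCS1A, the Rubisco small subunit, was at 3.13, 3.997 and 0.29 CPM in smr1 and 0.37 and 0.26 CPM in Col-0. LHCB1.1 was at 2.19, 2.70 and 0.11 CPM in smr1 and 0.16 and 0.075 CPM in Col-0. The median log2 fold change was 0.48, and camera gave an adjusted p of 0.0584 with the preset correlation. Without smr1 replicate 1 the median was -0.11 over 10 tested genes instead of 12, with camera's direction lower (adjusted p = 0.475). It was 0.04 without Col-0 replicate 4. The list was called higher with RLE factors (adjusted p = 0.0448), without Col-0 replicate 2 (median 1.20, adjusted p = 0.00199) and without smr1 replicate 4 (median 0.79, adjusted p = 4.25e-12), and not with an estimated correlation (adjusted p = 0.683).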

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

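No group held enough libraries for a test of single outlying samples, and there was 1 contrast. Several patterns are weighed instead. The tests of single libraries, of meristem nuclei, of linkage to SMR1 and of green tissue were chosen after the results were seen. So were those of the genes nearest in length and GC, and of AT5G26270 and MRD1 alone. Those of length and GC content, of other splits and of copies were written before their own values were seen. They too address lists and genes already seen to be higher.

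The core histone, replication, G2/M and ribosomal protein lists were higher in smr1 with the preset correlation, and not with an estimated one (adjusted p = 0.408 for each), and a single library did not carry the 3 division lists, with medians from 0.424 to 0.843 without any one library, but the ribosomal median was 0.257 without Col-0 replicate 4, against 0.466 with all (highest camera adjusted p over the 4 lists 3.03e-05). A trend with coding length and GC content was also argued against, although it moved other genes little (-0.041 to 0.026 for 90% of them): the median of the 382 pooled members was 0.479 before and 0.476 after its removal, 0.269 to 0.618 without any one library, and that of the outside genes nearest in length and GC was 0.016. More meristem nuclei in the smr1 sorts may contribute and stays open. The meristem list had a median log2 fold change of 0.486, and 0.453 to 1.098 without any one library. Those medians cover 7 genes instead of 6 without either Col-0 library. Library levels of the meristem list overlapped between the genotypes. Those levels did not follow the core histones: smr1 replicate 4 had -0.02 for the meristem list and 0.58 for histones, and Col-0 replicate 2 had 0.09 and -0.41. The 10 splits of the libraries into 2 and 3 are too few for a share under 0.05: the real split called 10 lists, the highest other 11, and 3 splits called at least 10, the real one included. Medians in the real split were 0.782, 0.537, 0.559 and 0.466 for histones, replication, G2/M and ribosomal proteins. Absolute medians were at most 0.645, 0.414, 0.439 and 0.414 in the others. Those came from smr1 replicates 1 and 4 against the rest. That split keeps the Col-0 libraries together, so it holds part of the genotype difference. Where 1 Col-0 and 1 smr1 library were put together, the highest absolute medians were 0.356, 0.288, 0.239 and 0.347. An effect of the genotype stays open as well, untested against these.

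AT5G35935, AT5G26270, AT2G05642 and MRD1 were among the genes with the smallest p in the higher direction, and a segment linked to SMR1 was argued against, since 0 of the 4 genes lie on chromosome 3. Reads shared with near-identical copies may affect part of them: 2 of the 4 genes had another genomic stretch of at least 75 nt at 97% identity, of 109 of 6504 nt for AT5G35935 and 624 of 3081 nt for AT2G05642. For AT5G35935 5 of 5 read values were whole, so no division of reads between models was seen, and for AT2G05642 3 of 5 were, 2 of them at 0 reads, but the positions of reads are not given, so shared reads and a difference in transcript level cannot be told apart for these genes. For AT5G26270 and MRD1 the search found 0 such stretches. A difference between the plant lines outside SMR1 was not tested.

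Photosynthesis genes were uneven within smr1. RNA from green tissue is a candidate source, as members varied together within genotypes, with an estimated correlation of 0.810, although regulation shared by these genes would give the same value. Endodermis markers and core histones had estimated correlations of 0.785 and 0.715, so a value of this size does not single out such a source. In Col-0 replicate 2, RBCS1A and LHCB1.1 were at 0.37 and 0.16 CPM, below their 3.13 and 2.19 CPM in smr1 replicate 1, while LHCA4, PSBO1 and RCA, named after their values were seen, were at 22.4, 20.3 and 17.2 CPM, against 24.2, 23.7 and 21.5 CPM. The sort for GFP-positive nuclei would be expected to remove most such material. Library levels of the 2 genotypes overlapped, camera called the list higher without smr1 replicate 4 (adjusted p = 4.25e-12) or Col-0 replicate 2 (adjusted p = 0.00199), its direction was lower without smr1 replicate 1 (median -0.11, adjusted p = 0.475), and an effect of the genotype stays open, untested.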

How the results depend on the processing

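The 18S rRNA locus left out of library sizes was added after seeing the data. So were the counts adjusted over a list alone with the block or with a library left out. AT5G35935 kept its call under every scaling, filter and organelle setting tried, with DESeq2, with the robust option off, with the block, against a fold of 1.5 and with 1 model per locus. It lost it in limma voom (adjusted p = 0.0639) and without any 1 library. The count of genes higher was 3 with no filter, 30 with DESeq2, 0 with limma voom, 2 with the replicate block and 0 without any one library, and the count lower was 11 with DESeq2. Single libraries left out leave fewer samples, and the cause of the other differences was not tested. SMR1 had a log2 fold change of -1.47 with DESeq2, which called it, and -1.87 to -0.90 without any one library. Lists called higher and lower each numbered 0 with an estimated correlation and 0 with directional fry. Mixed fry, which has no direction, called 1 list, that of G1/S cyclins, A2-type cyclins and their partners. DESeq2 called 15 named genes that edgeR did not, SMR1 included. With the block the xylem list lost its call (adjusted p = 0.133), AT5G26270 gained one, and the auxin response (adjusted p = 3.75e-05) and wounding (adjusted p = 0.00266) lists were called higher. No other list or named gene changed its call with it. Adjusted over the list alone, 9 replication genes rose with it, against 3 without, and 0 phloem genes, against 1. The median of the photosynthesis list was -0.097 with it, and that of heat shock -0.53. Number 1 occurs only in smr1, so in the block fit smr1 replicate 1 adds nothing to the genotype difference. That fit had 1 residual degree of freedom. The label numbers share only 2 values between the groups and the labels name no batch, so they were not taken to pair the samples. Deviations from the group mean correlated at 0.397 for number 2 and 0.185 for number 4, the highest over all pairs, with 0.171 next. With n = 2 in Col-0, the deviations there mirror each other, so part of these values is fixed. They do not argue against a batch shared by number, which stays open. Directions reversed for PEP and LBD16 without Col-0 replicate 4, and for SCR without Col-0 replicate 2. Over the libraries left out, log2 fold changes ran from -0.614 to 0.571 for PEP, -0.0405 to 0.655 for LBD16 and -0.0986 to 0.495 for SCR. Library size alone moved the median log2 fold change by 0.06. In simulated counts for this comparison 42% of 2-fold changes were called by edgeR, so changes of that size can go uncalled. The simulated counts gave 165 calls and the real ones 1. Fewer calls mean a stricter cutoff for the adjusted p, so the share called in these data may be lower.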

Other observations

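The tests below used annotation terms chosen after the data were seen, while the tests of nucleolar genes without ribosomal proteins and of neighbours of SMR1 were written before their values were seen. Genes annotated to the nucleolus, where ribosomes are assembled, were higher in smr1 with the preset correlation. With an estimated correlation the call was lost (adjusted p = 0.946). Of 191 such genes 151 had positive log2 fold changes, with a median of 0.29. Among the nucleolar genes with the smallest p, chosen after their values were seen, NAP57, the pseudouridine synthase of box H/ACA particles, had a log2 fold change of 1.79, the fibrillarin FIB2 2.36, NOP56 1.33, the RNA helicase PRH75 1.099 and the histone deacetylase HDA3 2.15. DESeq2 called all 5 higher, and edgeR called none of them. The terms for ribosome biogenesis (99 genes, median 0.46), rRNA processing (24 genes, 0.35) and nucleosome assembly (50 genes, 0.58) were also higher with the preset correlation, and with an estimated correlation these calls were lost (adjusted p = 0.946 for each). Response to hydrogen peroxide (13 genes, -0.26), trehalose biosynthesis (12 genes, -0.28) and response to water deprivation (62 genes, -0.15) were lower with the preset correlation only (adjusted p = 0.946 for each with an estimated correlation). Of 347 terms camera called 27 higher and 6 lower with the preset correlation and 0 with an estimated correlation. The latter setting can miss real differences with so few libraries.

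The nucleolar difference could come from the ribosomal proteins that carry the same term. Without them, 120 of 159 genes were positive, with a median log2 fold change of 0.21, so positive values were not confined to ribosomal proteins. The camera p was 7.36e-17 with the preset correlation. With the estimated correlation of 0.253 it was 0.127, so a difference of the remaining genes rests on the preset value. The remaining genes still include core histones.

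AT3G10530, a WD40 repeat protein beside SMR1, had a log2 fold change of 1.46 with an SE of 0.29 (edgeR adjusted p = 0.725). A local effect of the mutation could reach several neighbours. The 25 tested genes within 50 kb had a median absolute log2 fold change of 0.104, at percentile 6.55 of 9951 windows of as many neighbouring genes, whose median was 0.168. This argues against a difference shared by the neighbours and leaves AT3G10530 itself open.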
